A study of Mus musculus with 6 samples.

How the data were processed

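Total RNA of tumour biopsies from a mouse model of lung squamous cell carcinoma had been sequenced, with 3 libraries labelled PSC and 3 labelled PSCN. Per the labels' protocols, stranded total RNA libraries were made and read at a length of 76 nt, and the submitters' processing notes name Trimmomatic, HISAT2, StringTie and DESeq2 without versions, with GRCm38 as the genome. How strand entered the counting is not given in the sources used here, so genes that overlap cannot be told apart by their counts. The deposited table holds estimated counts per gene symbol from the authors, already as whole numbers, and was read as the count table that had been planned for. The authors also deposited DESeq2's mean normalized signal per gene, log2 fold changes of PSCN over PSC with standard errors, and p-values with their adjusted p-values. The mean recomputed from the counts with median-of-ratios size factors differed from the deposited mean signal by at most 0.0005.

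The table has 46937 symbols, of which 14737 had no count in any library, and 45315 matched GENCODE M21 once. Some symbols follow human naming, such as CYP2F1, so a symbol may stand for more than 1 mouse gene. Columns of the table were matched to the labels by letter and number, a match the labels do not spell out. Total counts ranged from 69563622 to 72807077, and sequencing reads without molecular identifiers are not independent molecules.

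Genes were filtered with filterByExpr, which left 21201, normalized with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The residual degrees of freedom were 4 and the prior degrees of freedom 2.03. SE is the size of the log2 fold change divided by the square root of F. Levels are CPM, counts scaled to TMM-adjusted library sizes. An exact permutation test of 3 against 3 libraries cannot go below a two-sided p of 0.1, so none was used for single genes.

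The 54 gene lists, the test, the filter and the rule for naming genes were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, where only mast cell genes passed (adjusted p = 0.0128). Reactome pathways of 10 to 300 measured genes came from fgsea 1.28.0, with 6216 of 7111 gene identifiers matched. A list score is the mean over its genes of log2 CPM minus that gene's mean over the 6 libraries. Named genes were the genes of the model, up to 12 per direction among genes past the threshold with no overlap between groups and a mean of at least 5 CPM in the higher group (predicted genes, pseudogenes and plain identifiers left out), and up to 4 members with the smallest p of each list described. Since fewer than 5 genes passed, the 10 with the smallest p were named too. GM47308 came in by that last part. XIST, DDX3Y, RAB11A, RPS2-PS10, RPS2-PS6 and MMP13's levels per library, and genes of the closing section outside these lists, were chosen after their values were seen. AY036118 and CT010467.1 were not named by these rules.

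The alternatives were RLE and upper quartile normalization, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a filter of 1 CPM in at least 3 libraries, each library left out in turn, a block for replicate numbers, and the list tests above. Alternatives added after seeing the data were PSC library 3 as the only PSC library, sex as a covariate, edgeR with adjusted deviances and limma-voom without quality weights. With PSC library 3 as the only PSC library, PSC has no spread of its own. Calls and counts of that fit rest on the spread among PSCN libraries and do not test the groups. The fits were tested on simulated data with 21201 genes, of which 20704 passed the filter. For PSCN against PSC, edgeR recovered 35% of genes changed 4-fold and 82.8% of those changed 16-fold, with 5 false calls among 123. DESeq2 recovered 78% and 93.9%, with 145 false calls among 321, and limma-voom with quality weights 28% and 84.8%, with 3 among 116. The list with a simulated shift was called and 0 of the others were. Genes were drawn independently there, while correlations estimated within lists of the real data reached 0.93. The simulation therefore says little about false list calls in these data. Some genes that met these rules or were looked at afterwards are not reported here.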

Results

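RNA sequencing of total RNA from 6 mouse lung squamous cell carcinoma biopsies was analysed. The tumours came from a genetic model with constitutively active PI3K (PIK3CA H1047R), overexpressed SOX2 and deletion of CDKN2A and CDKN2B, called PSC, which is the control group. Per the labels, PSCN tumours carry the same alterations and also express NSD3 T1242A, a mutant of the histone H3 lysine methyltransferase NSD3. Each group held 3 libraries, and the single comparison of the series asks how the tumours' transcripts differ when the NSD3 mutant is expressed. The labels do not say that each biopsy came from a separate mouse, so the p-values measure only the spread between these samples. Total counts were 69563622, 69717200 and 72281119 in PSC libraries 1, 2 and 3 and 72807077, 70979353 and 72740447 in PSCN libraries 1, 2 and 3. Between 25778 and 27880 genes had at least 1 count in a library. Gene symbols are given in capitals, as in the count table. PSC library 3 lay closer to the other group than to its own: across the 21201 genes tested, its mean correlation of log2 CPM (counts scaled to library size) was 0.941 with the PSCN libraries and 0.908 with the other PSC libraries, genes not being independent replicates. The female transcript XIST stood at 1088 and 1034 CPM in PSC libraries 2 and 3 and between 0.89 and 2.4 CPM in the other 4, which instead had the Y-linked DDX3Y at 54.6 to 84.7 CPM. PSC library 1 and the 3 PSCN libraries therefore came from male mice, and PSC libraries 2 and 3 from female mice.

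NSD3, the gene altered in PSCN, was higher in each PSCN library than in any PSC library. It stood at 92.7 ± 11.5 CPM in PSC (SD, n = 3) and at 1223 ± 615 CPM in PSCN (SD, n = 3), a log2 fold change of 3.72 (SE 0.41). Its adjusted p was 0.137 over the 21201 genes tested with edgeR and 0.000619 adjusted over the list alone, the list being the 6 genes of the model. The levels were 79.7, 96.7 and 101.7 CPM in PSC and 820.7, 917.8 and 1931.8 CPM in PSCN, so the libraries' NSD3 levels follow their labels. NSD3 (ENSMUSG00000054823.16) lies on chromosome 8 from 25601601 to 25719667 in GRCm38. The count does not separate a transgene from the mouse's own gene. SOX2, the squamous lineage factor (chromosome 3, 34650405 to 34652461), stood at 210.2 ± 73.3 CPM in PSC and 281 ± 148 CPM in PSCN, a log2 fold change of 0.42 (SE 0.47). PIK3CA had a log2 fold change of 0.39 (SE 0.18), and of 0.23 to 0.51 without each library in turn. CDKN2A, a cell cycle inhibitor locus deleted in the model (chromosome 4, 89274471 to 89294653), was low in both groups, with 4.08 ± 1.49 CPM in PSC and 1.96 ± 0.774 CPM in PSCN. CDKN2B, its deleted neighbour, was at or below 0.94 CPM in 5 libraries and at 86.1 CPM in PSCN library 1. A biopsy can hold cells without the labelled deletion, so this count does not tell whether tumour cells there kept the gene. MTAP, next to CDKN2A and not part of the deletion as labelled, differed by 0.23 (SE 0.19) on the log2 scale, and by 0.13 to 0.39 without each library in turn. None of SOX2, PIK3CA, CDKN2A, CDKN2B and MTAP passed the test, over all genes or adjusted over the list alone.

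**Figure D1:**
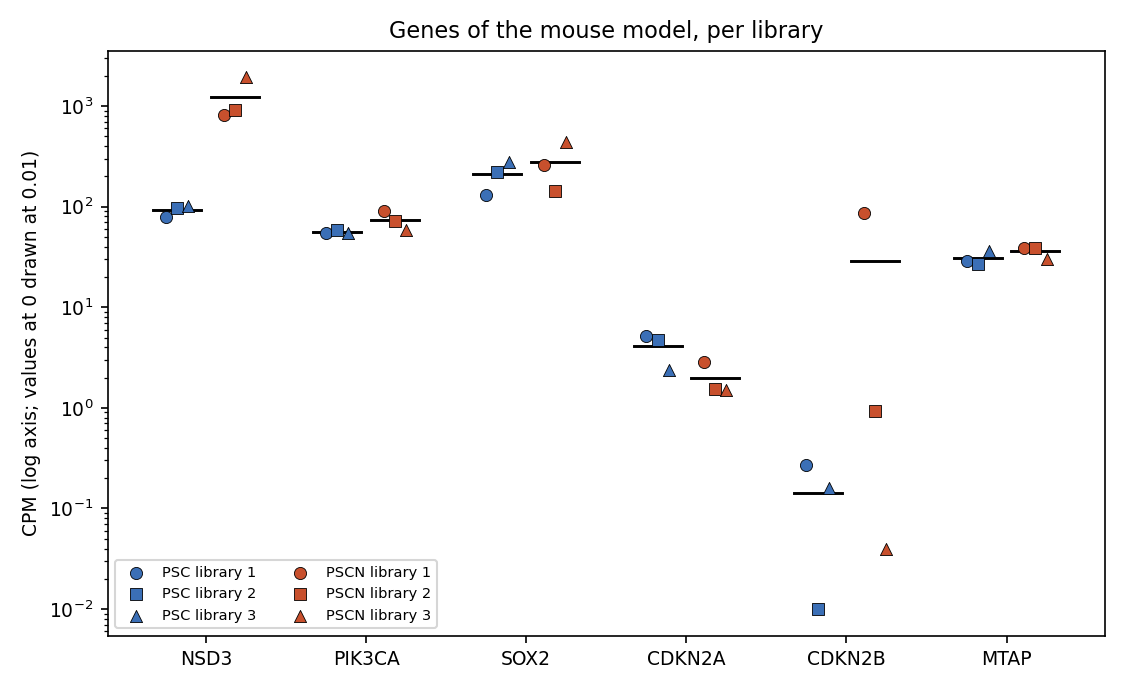
CPM of the 6 genes of the mouse model (log axis) in each library, PSC in blue and PSCN in red, with bars at the group means (n = 3 each). NSD3 lies at 79.7 to 101.7 CPM in PSC and at 820.7 to 1931.8 CPM in PSCN, and CDKN2B stands at 86.1 CPM in PSCN library 1.

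The only gene past an adjusted p of 0.05 in edgeR was GM47308, a predicted microRNA gene within RAB11A (chromosome 9, 64726624 to 64726730), with 2, 1 and 1 counts in PSC libraries 1 to 3 and 724, 1232 and 910 counts in PSCN libraries 1 to 3 (adjusted p = 0.0274). Its host RAB11A had a log2 fold change of 0.86 (SE 0.33), and reads of the pair may not be separable. The count was 1 gene higher and 0 genes lower in PSCN. At an unadjusted p under 0.05 there were 2010 higher and 2579 lower genes, where about 1060 in all would be met with no effect and no structure among the samples. Other splits of the libraries into 3 and 3 gave from 169 to 3600 such genes, against 4589 for the real split. Among the other splits, counts above 1060 came only from those that kept PSC libraries 1 and 2 together (3600, 1505 and 1450). Each other split still divides the genotypes unequally, so these counts do not tell how much of the excess belongs to the genotype. All 3 PSCN libraries lay above all 3 PSC libraries in 3231 genes and below them in 2835, together 28.6% of those tested, where chance gives 10%. DESeq2 called 1126 genes higher and 1834 lower, and limma-voom with quality weights called 1788 and 1238, the weights being 0.83, 2.92 and 0.36 in PSC libraries 1 to 3 and 0.81, 0.9 and 1.54 in PSCN libraries 1 to 3. Without these weights, an alternative added after seeing the data, limma-voom called 0 higher and 0 lower. On data simulated for this comparison, 4.1% of the edgeR calls, 45.2% of the DESeq2 calls and 2.6% of the limma-voom calls were false. Those genes were drawn independently and with no library apart from its group, so these shares are not error rates of the calls above. Without PSC library 3, edgeR called 751 higher and 1195 lower genes, and NSD3 then passed with an adjusted p of 0.0403.

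The other 9 of the 10 genes with the smallest unadjusted p did not pass the adjusted threshold. PTTG1IP, a membrane protein that binds securin, stood at 60.8 ± 4.22 CPM in PSC and 227 ± 12 CPM in PSCN (SD, n = 3 each; log2 fold change 1.90, SE 0.13, adjusted p = 0.0614). The pseudogene GM5921 stood at 1.23 and 22.5 CPM (adjusted p = 0.0614) and the noncoding transcript AI506816 at 3.13 and 105 CPM (adjusted p = 0.137). RPL30, a ribosomal protein gene, stood at 60.2 and 197 CPM. Among those with lower values in PSCN, DTX1, a Notch pathway ubiquitin ligase, had a log2 fold change of -2.57 (SE 0.24). The dynein adaptor BICD1 had -2.93 (SE 0.29), the carboxylesterase CES1E -3.63 (SE 0.36), the calcium channel subunit CACNA1E -3.45 (SE 0.35) and the phosphatase inhibitor PPP1R1B -4.65 (SE 0.50). CES1E belongs to a family of similar genes and GM5921 is a processed pseudogene, so their counts are uncertain. The adjusted p of RPL30, DTX1, BICD1, CES1E, CACNA1E and PPP1R1B was 0.137 each.

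**Figure D2:**
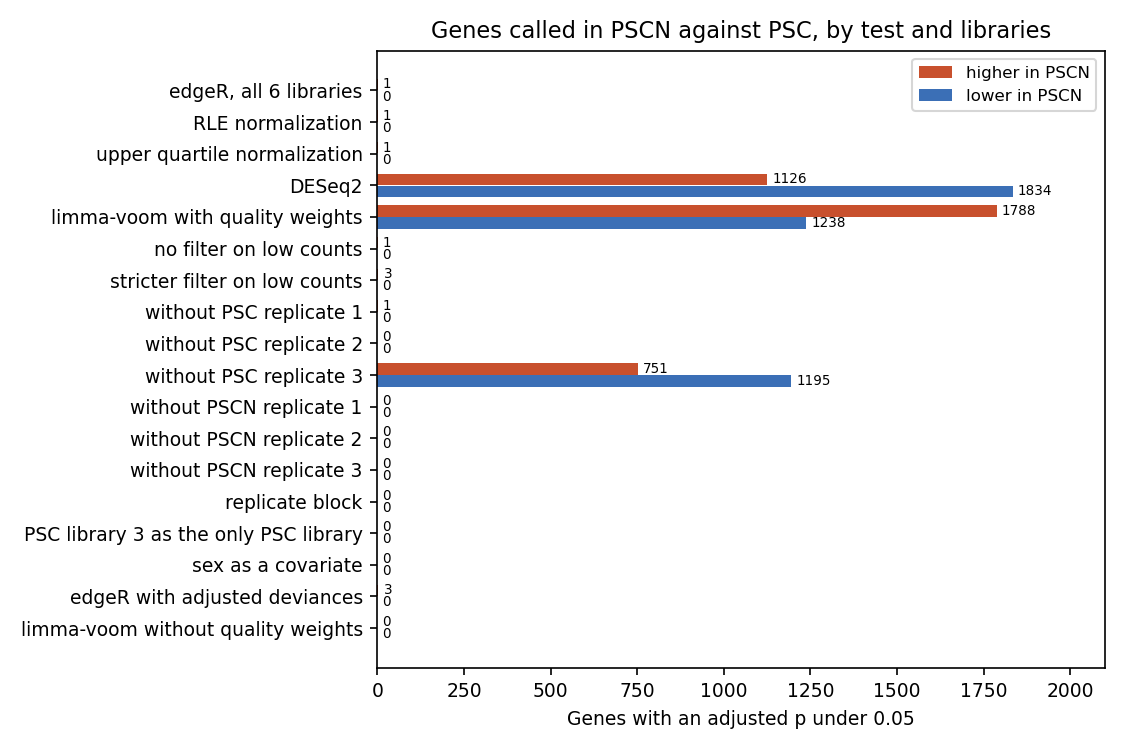
Number of genes with an adjusted p under 0.05 in PSCN against PSC (bars start at 0), by test, normalization, filter and libraries used. The edgeR test of all 6 libraries called 1 gene, and without PSC replicate 3 it called 751 higher and 1195 lower.

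Of 54 gene lists fixed before the data were examined, 16 were higher and 11 lower in PSCN with camera at a preset inter-gene correlation of 0.01. No list stayed past the threshold with an estimated correlation, where the lowest adjusted p was 0.549. GM47308 is in none of the lists, so 0 members of each passed over all genes tested. Genes of squamous differentiation, the keratinizing and cornifying programme of stratified epithelium, rose in PSCN as a list (adjusted p = 8.77e-12 and adjusted p = 0.578 with an estimated correlation). All 31 measured members had positive log2 fold changes, with a median of 2.61, and 2 passed adjusted over the list alone. These were the epidermal secreted protein SBSN, at 15.2 ± 6.58 CPM in PSC and 269 ± 185 CPM in PSCN, and the corneodesmosome protein CDSN, with a log2 fold change of 4.43 (SE 0.88). SPRR1B, a cornified envelope precursor, had a log2 fold change of 7.60 (SE 2.10) and did not pass. The list of basal squamous cell genes also rose (25 members, 23 positive, median log2 fold change 1.43, adjusted p = 2.26e-05 and adjusted p = 0.578 with an estimated correlation), and 0 members passed adjusted over the list alone. In it, LAMA3, a chain of a basement membrane laminin, had a log2 fold change of 1.04 (SE 0.36), and the desmosome-associated PERP had 1.91 (SE 0.76). The list of SOX2-linked squamous regulators was not called (adjusted p = 0.539), with FOXA1 at -0.84 (SE 0.20), FOXA2 at -2.07 (SE 0.67) and OVOL1 at 2.30 (SE 0.88). Leaving out each library in turn, the median of this list ran from 0.03 to 0.68, and OVOL1 from 1.72 to 3.60. The score of squamous differentiation, the mean log2 CPM relative to all 6 libraries, was -4.10, -1.90 and 0.28 in PSC libraries 1 to 3 and lay between 1.37 and 2.97 in PSCN. Without PSC library 3 its median was 5.03, and that of the basal list was 2.33, against 0.88 without PSC library 1. With PSC library 3 as the only PSC library, a choice made after seeing the data, the basal median was 0.47 and that of squamous differentiation 1.57. The basal score of PSC library 3 was 0.70, above that of PSCN library 3 at 0.07. Within PSC the ciliated cell score ran the other way from that of squamous differentiation, at 3.26, 2.10 and -1.35 in PSC libraries 1 to 3. A change of expression in tumour cells was not separated from a different mix of cell types.

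Growth lists were higher in PSCN, as were ribosomal protein, replication histone and immediate early genes, 3 lists that had been fixed as signs of RNA quality. MYC targets had 43 of 45 members positive (median log2 fold change 0.60, adjusted p = 2.9e-11 and adjusted p = 0.578 with an estimated correlation). Examples were the ribosome assembly factor NOP56 at 0.87 (SE 0.22), the spermidine synthase SRM at 1.04 (SE 0.28) and the nucleolar chaperone NPM1 at 0.95 (SE 0.28), none of which passed adjusted over the list alone. Ribosomal protein genes were positive in 43 of 43 (median 0.71, adjusted p = 3.88e-18 and adjusted p = 0.549 with an estimated correlation), and 40 passed adjusted over the list alone, among them RPL30 at 1.71 (SE 0.17), RPS18 at 1.49 (SE 0.23) and RPL26 at 0.99 (SE 0.19). The noncoding symbols AY036118 and CT010467.1 together took 4.12, 4.02 and 2.71% of the counts in PSC libraries 1 to 3 and 1.79, 2.52 and 1.05% in PSCN libraries 1 to 3. RPS2 stood apart at 4.91 (SE 0.65), while its pseudogene RPS2-PS10 had -1.52 (SE 0.22) and RPS2-PS6 had 1.87 (SE 0.24), and reads may be split between them. The E2F replication list was positive in 39 of 40 genes (median 0.56, adjusted p = 1.17e-07 and adjusted p = 0.578 with an estimated correlation), with the chromatin assembly subunit CHAF1B at 0.88 (SE 0.31) and E2F2 at -0.67 (SE 0.21). Its median was 0.33 without PSC library 2. The mitosis list was positive in 38 of 40 genes (median 0.85, adjusted p = 5.78e-09 and adjusted p = 0.578 with an estimated correlation), with the condensin subunit NCAPD2 at 0.88 (SE 0.26) and the kinase AURKB at 0.87 (SE 0.30). In both of these lists 0 members passed adjusted over the list alone. Replication histones were positive in 17 of 18 (median 0.95, 1.47 without PSC library 3, adjusted p = 5.6e-07 and adjusted p = 0.549 with an estimated correlation), including HIST1H1C at 0.67 (SE 0.20). The list of immediate early and stress genes rose as well (median 0.46, adjusted p = 0.00588 and adjusted p = 0.578 with an estimated correlation), with FOS at 0.78 (SE 0.20) and KLF4 at 1.37 (SE 0.40). Its median was 0.70 without PSC library 3 and 0.30 without PSCN library 3. With PSC library 3 as the only PSC library the median was 0.18 for the mitosis list and 0.15 for the immediate early list. The medians there were 0.23 for MYC targets, 0.19 for the E2F list, 0.38 for replication histones and 0.46 for ribosomal proteins. The mitosis score of PSC library 3 was 0.26, above that of PSCN library 1 at 0.17. MYC target scores were -0.41 and -0.56 in PSC libraries 1 and 2, where ciliated cell scores were 3.26 and 2.10, and 0.03 in PSC library 3. These rises too were not separated from a different mix of cell types.

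Most metabolic lists were higher as well, but that of the unfolded protein response was not called (median log2 fold change 0.13, adjusted p = 0.207). It was called with limma-voom with quality weights (median 0.28, adjusted p = 0.044). Cholesterol synthesis was positive in 24 of 24 genes (median log2 fold change 1.17, adjusted p = 8.95e-10 and adjusted p = 0.549 with an estimated correlation), and 19 passed adjusted over the list alone. MSMO1, which removes methyl groups from sterol precursors, stood at 62.5 ± 7.42 CPM in PSC and 199.9 ± 80.8 CPM in PSCN (SD, n = 3 each). The squalene synthase FDFT1 had a log2 fold change of 1.32 (SE 0.26) and the lanosterol synthase LSS 1.12 (SE 0.26). Glycolysis was positive in 16 of 16 (median 1.57, adjusted p = 1.17e-07 and adjusted p = 0.549 with an estimated correlation), and 11 passed adjusted over the list alone, including GPI at 1.37 (SE 0.29), ALDOA at 1.30 (SE 0.37) and PKM at 1.60 (SE 0.46). The mTORC1 list was positive in 43 of 50 (median 0.75, adjusted p = 1.32e-08 and adjusted p = 0.549 with an estimated correlation). The ATF4 amino acid response list was positive in 19 of 21 (median 0.73, adjusted p = 9.3e-06 and adjusted p = 0.549 with an estimated correlation). The same 2 genes passed adjusted over each of these lists alone: CHAC1, which breaks down glutathione, at 2.53 (SE 0.35), and the asparagine synthetase ASNS at 1.33 (SE 0.20). ATF4 itself was at 0.63 (SE 0.17). The hypoxia list rose (20 of 24 positive, median 0.89, adjusted p = 9.56e-05 and adjusted p = 0.549 with an estimated correlation), with ANKRD37 at 1.20 (SE 0.22), the only member past the threshold adjusted over the list alone, and NDRG1 at 2.51 (SE 0.75). Nuclear genes of oxidative phosphorylation had a smaller median of 0.28 (26 of 31 positive, adjusted p = 0.00231 and adjusted p = 0.663 with an estimated correlation), with the ATP synthase subunit ATP5F1B at 0.66 (SE 0.26). That call ended with sex as a covariate (median 0.25, adjusted p = 0.147), and the median was 0.11 with PSC library 3 as the only PSC library. The score of PSC library 3 lay above those of PSC libraries 1 and 2 in each list of this paragraph, for example 0.10 against -1.21 and -1.14 for glycolysis, where PSCN lay between 0.32 and 0.97. With that library as the only PSC library the medians were 0.74 for glycolysis, 0.71 for cholesterol synthesis, 0.36 for mTORC1, 0.36 for ATF4 and 0.52 for hypoxia.

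**Figure D3:**
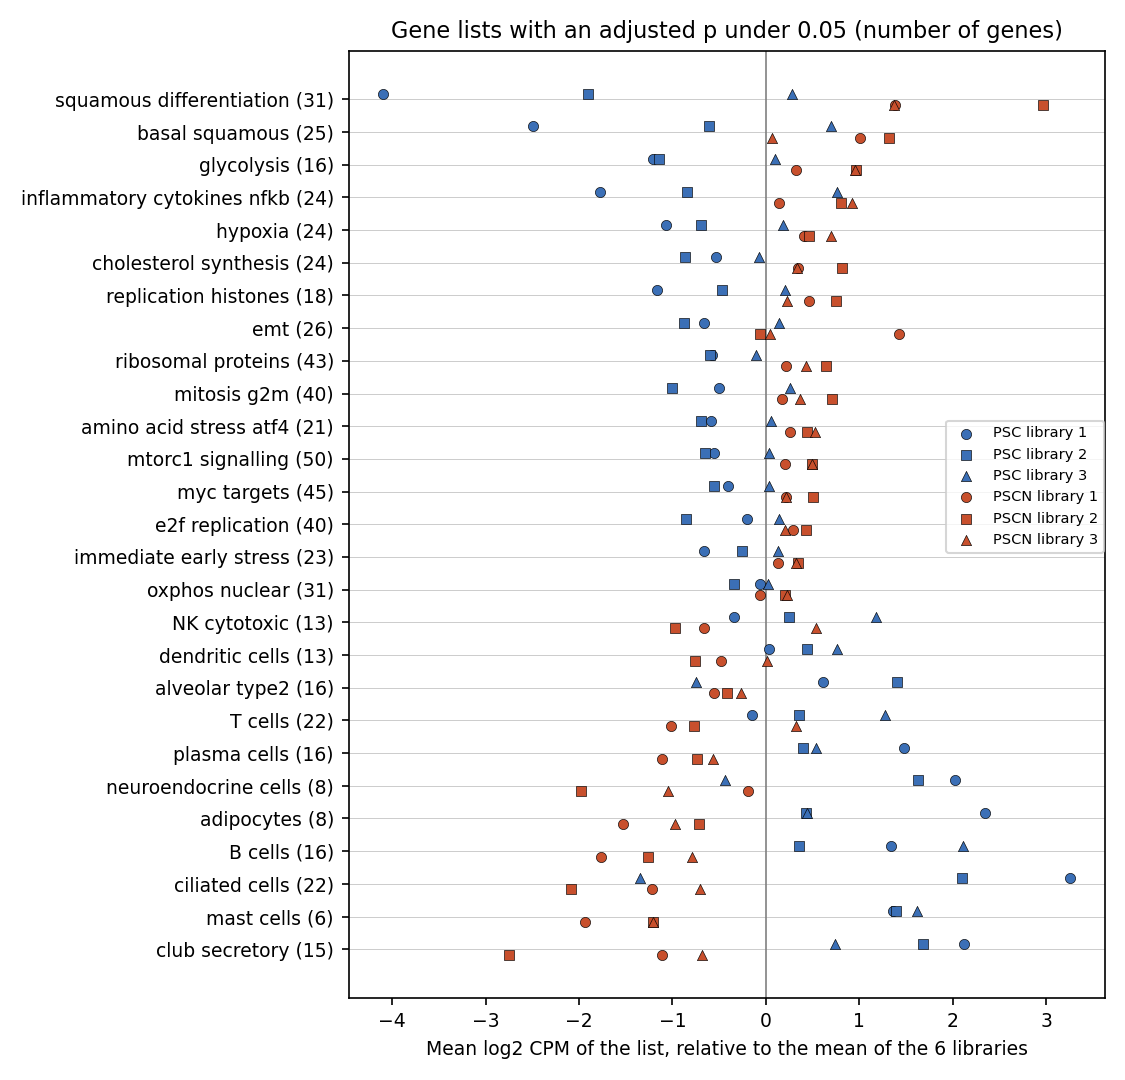
Mean log2 CPM of each called gene list relative to its mean over the 6 libraries, PSC in blue and PSCN in red, with 1 symbol per library and the number of genes in parentheses. PSC library 3 lies near the PSCN libraries for ciliated cells, at -1.35 against 3.26 and 2.10 in PSC libraries 1 and 2, and with the other PSC libraries for mast cells, at 1.62.

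Markers of the normal airway and lung were lower in PSCN. The club cell list, of secretory cells of the airway, fell (14 of 15 negative, median log2 fold change -3.54, adjusted p = 4.49e-06 and adjusted p = 0.549 with an estimated correlation), and 12 members passed adjusted over the list alone. The secretoglobin SCGB3A1 stood at 501 ± 157 CPM in PSC and 28.7 ± 20 CPM in PSCN (SD, n = 3 each). The mucin MUC5AC had a log2 fold change of -3.97 (SE 0.83) and the cytochrome CYP2F1 -2.87 (SE 0.73). The club median was -1.39 with PSC library 3 as the only PSC library. Ciliated cell genes fell (22 of 22 negative, median -3.75, adjusted p = 4.97e-06 and adjusted p = 0.578 with an estimated correlation), and 20 passed adjusted over the list alone, among them the ciliogenesis regulator MCIDAS at -3.28 (SE 0.50), PIFO at -4.07 (SE 1.08) and the axonemal dynein DNAI1 at -4.24 (SE 1.24). DNAI1 stood at 41.9, 18.1 and 1.2 CPM in PSC libraries 1 to 3 and between 0.6 and 1.6 CPM in PSCN. With PSC library 3 as the only PSC library, a choice made after seeing the data, the ciliated median was 0.24. Alveolar type 2 genes, of the surfactant-making cells, fell (15 of 16 negative, median -1.4, adjusted p = 0.0107 and adjusted p = 0.634 with an estimated correlation), with the lipid transporter ABCA3 at -1.64 (SE 0.36) and SFTPD at -1.46 (SE 0.34) passing adjusted over the list alone. The alveolar type 2 median was 0.34 with PSC library 3 as the only PSC library. The call ended without PSC library 2 (median -0.57, adjusted p = 0.184) and without PSCN library 1 (median -1.26, adjusted p = 0.0938). Neuroendocrine genes fell (8 of 8 negative, median -1.79, adjusted p = 0.00527 and adjusted p = 0.578 with an estimated correlation), with the granin CHGB at -3.57 (SE 0.88). Their median was -0.03 with PSC library 3 as the only PSC library. Adipocyte genes fell (8 of 8 negative, median -2.45 and -1.63 without PSC library 1, adjusted p = 0.00231 and adjusted p = 0.549 with an estimated correlation), with PPARG at -1.82 (SE 0.30), and their median was -1.31 with PSC library 3 as the only PSC library. The alveolar type 1 list was not called (median -0.55, adjusted p = 0.835), with IGFBP2 at 2.28 (SE 0.53) and HOPX at 1.01 (SE 0.39), and neither were the lists of fibroblasts (median 0.42, adjusted p = 0.490), endothelium (median -0.63, adjusted p = 0.194), mesothelium (median -0.89, adjusted p = 0.0553) and striated and heart muscle (median -4.26, adjusted p = 0.181). For alveolar type 1 camera's direction was up and for fibroblasts down, opposite to their medians. In the mesothelium list MUC16 had -7.52 (SE 1.19) and MSLN -3.19 (SE 0.93), both past the threshold adjusted over the list alone. The mesothelium median was 0.03 without PSC library 3 and -1.81 without PSCN library 1, and the muscle median was -0.64 without PSC library 1. Other settings did call these lists. Fibroblasts passed without PSCN library 1 (median -1.05, adjusted p = 0.000945), endothelium with DESeq2 (adjusted p = 0.038), with limma-voom with quality weights (adjusted p = 0.00211) and without PSC library 3 (median -1.02, adjusted p = 2.47e-05), and muscle with DESeq2 (adjusted p = 3.96e-05) and without PSC library 3 (adjusted p = 0.0346). Mesothelium passed with DESeq2 (adjusted p = 0.00852), with the stricter filter (adjusted p = 0.0281) and without PSC library 1 or 2 or PSCN library 1 or 2 (adjusted p = 0.0429, 0.0239, 0.0414 and 0.0454).

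Lymphoid and mast cell markers were lower in PSCN. The B cell list fell (16 of 16 negative, median log2 fold change -2.69, adjusted p = 5.1e-10 and adjusted p = 0.549 with an estimated correlation), and 15 members passed adjusted over the list alone. The antigen receptor chains CD79A and CD79B had log2 fold changes of -3.33 (SE 0.60) and -2.68 (SE 0.48), and the kinase BLK had -2.71 (SE 0.46). Plasma cell genes fell (14 of 16 negative, median -1.84, adjusted p = 4.59e-05 and adjusted p = 0.549 with an estimated correlation), 10 of them passing adjusted over the list alone against 1 in the other direction. IGHM, the IgM heavy chain, stood at 150 ± 76.8 CPM in PSC and 18.3 ± 3.11 CPM in PSCN (SD, n = 3 each). Mast cell genes fell (6 of 6 negative, median -3.83, or -3.15 with the 2 members that had no count in PSCN set at 3 counts per library, adjusted p = 1.14e-05 and adjusted p = 0.549 with an estimated correlation). Of these, 5 passed adjusted over the list alone, including the histidine decarboxylase HDC at -2.32 (SE 0.47). HDC had 14453, 10319 and 7063 counts in PSC libraries 1 to 3, far above CPA3, so its level may not come from mast cells. It is also in the neutrophil list, as the only member past the threshold adjusted over that list alone. CPA3, the mast cell carboxypeptidase, had 33, 54 and 84 counts in PSC and 2, 3 and 3 in PSCN. This call ended with a stricter filter on low counts (median -1.26, adjusted p = 0.157). T cell genes fell as a list, with 0 members past the threshold adjusted over the list alone (22 of 22 negative, median -1.07, adjusted p = 0.000121 and adjusted p = 0.578 with an estimated correlation), with CD28 at -1.71 (SE 0.40) and CD4 at -1.4 (SE 0.46). Without PSC library 3 the T cell median was -0.46 and the call ended (adjusted p = 0.0729), and without PSCN library 3 the median was -1.68. The T cell median was -1.62 and the natural killer median -1.44 with PSC library 3 as the only PSC library. Dendritic cell genes fell (12 of 13 negative, median -0.99, adjusted p = 0.00231 and adjusted p = 0.578 with an estimated correlation), with XCR1 at -1.79 (SE 0.33) and FLT3 at -1.71 (SE 0.36) among the 4 past the threshold adjusted over the list alone, and lost the call without PSC library 3 (median -0.74, adjusted p = 0.0527). The list of natural killer cells (median -0.94, adjusted p = 0.0354 and adjusted p = 0.663 with an estimated correlation) lost its call without PSC library 3 (median -0.07, adjusted p = 0.512), PSCN library 1 (median -0.82, adjusted p = 0.183) or PSCN library 2 (median -0.70, adjusted p = 0.219). It was not called with DESeq2 (median -0.93, adjusted p = 0.0634) or limma-voom with quality weights (median -0.17, adjusted p = 0.268). Macrophage genes were not called (median -0.14 with camera's direction up, adjusted p = 0.803). With the sex of the mouse as a covariate, added after seeing the data, the T cell, dendritic, natural killer and alveolar type 2 calls ended (medians -0.24, -0.52, -0.03 and -1.03, adjusted p = 0.293, 0.194, 0.783 and 0.0564), as did that of oxidative phosphorylation, while the B cell, plasma, mast, club and ciliated lists passed. PSC library 1 is the only male PSC library, so the group difference in that fit rests on it.

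Lists of inflammatory and mesenchymal genes were higher with wide spread. NF-kappaB cytokines had 21 of 24 members positive (median log2 fold change 0.74, adjusted p = 0.00176 and adjusted p = 0.578 with an estimated correlation), and 0 passed adjusted over the list alone. Among these cytokines were the neutrophil attractant CXCL2 at 1.4 (SE 0.53, 1.04 to 2.13 without each library in turn) and IL6 at 1.78 (SE 0.61, 1.11 to 2.08). Their median was 0.37, 0.40 and 1.79 without PSC libraries 1, 2 and 3 and 0.46 without PSCN library 3. With PSC library 3 as the only PSC library it was -0.07. The neutrophil list was not called (median 0.73, adjusted p = 0.0553), but passed without PSC library 2 (adjusted p = 0.0239), PSC library 3 (median 1.63, adjusted p = 0.00474), PSCN library 1 (adjusted p = 0.0189) or PSCN library 2 (adjusted p = 0.0495). It also passed with upper quartile normalization (adjusted p = 0.0294), limma-voom with quality weights (adjusted p = 0.0253) and no filter (adjusted p = 0.0153). With the replicate block it passed too (median 1.06, adjusted p = 0.00683). Without PSC library 1 its median was 0.34 and it did not pass. Its scores were -1.64, -0.58 and 0.56 in PSC and 0.05, 0.66 and 0.95 in PSCN, beside -1.78, -0.84 and 0.76 and 0.14, 0.80 and 0.92 for the cytokine list. Genes of epithelial-mesenchymal transition had 23 of 26 positive (median 0.74, adjusted p = 0.0126 and adjusted p = 0.578 with an estimated correlation). But the call ended without PSCN library 1 (median 0.23, adjusted p = 0.293), and the median was 0.31 with PSC library 3 as the only PSC library. MMP13, a collagenase of that list, stood at 1674.5 CPM in PSCN library 1 and at 105.4 and 70.3 CPM in PSCN libraries 2 and 3.

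Genes of the chromatin lists nearest to NSD3's function were not called as groups. Writers, readers and erasers of any methylation at the histone residue that NSD3 acts on had 10 positive and 12 negative members (median log2 fold change -0.05 with a mean of 0.13, adjusted p = 0.829). NSD3 was the only member past the threshold adjusted over the list alone. The demethylase KDM4B had 0.62 (SE 0.17), the methyltransferase SMYD2 0.65 (SE 0.22) and the reader PHF1 -0.77 (SE 0.21). Polycomb genes had a median of 0.18 (adjusted p = 0.349), with AEBP2 at 0.67 (SE 0.24). Partners of NSD3 and bromodomain proteins had a median of 0.03 with camera's direction down (adjusted p = 0.929), and KMT2A, a methyltransferase of the mixed lineage leukaemia complex, stood at 161 ± 6.79 CPM in PSC and 98.4 ± 10.6 CPM in PSCN (SD, n = 3 each), past the threshold adjusted over the list alone (adjusted p = 0.0237). Neighbours of NSD3 in the human amplified region had a median of 0.17 (adjusted p = 0.271), and of 0.10 to 0.28 without each library in turn. In that list the translation repressor EIF4EBP1 had 1.45 (SE 0.32), passing adjusted over the list alone, and the methyltransferase subunit ASH2L had 0.64 (SE 0.20).

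The signalling lists described here, apart from hypoxia and epithelial-mesenchymal transition, were not called. The growth factor feedback list, of transcripts set by FGFR, PI3K and MAPK signals, had a median log2 fold change of 0.15 (adjusted p = 0.388), with the receptor IL17RD at -1.53 (SE 0.35) and PIK3R1 at -0.58 (SE 0.18). The oxidative stress targets of NRF2 had a median of 0.22 (0.15 to 0.34 without each library in turn, adjusted p = 0.129), with HMOX1 at 1.25 (SE 0.26) and SRXN1 at 0.80 (SE 0.19). The p53 targets had 9 positive and 9 negative members (adjusted p = 0.804). In that list PLK2 stood at 79.8 ± 3.60 CPM in PSC and 219 ± 30.7 CPM in PSCN (SD, n = 3 each), and the cell cycle inhibitor CDKN1A had 1.14 (SE 0.23). These 2 genes and TP53INP1, at -1.10 (SE 0.24), passed adjusted over the list alone.

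Of 867 Reactome pathways, 267 were higher and 31 lower in PSCN with camera at the preset correlation, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.709. Translation (161 genes, median log2 fold change 0.63, adjusted p = 3.27e-23), M Phase (213 genes, median 0.39, adjusted p = 1.7e-10), DNA Replication (98 genes, median 0.39, adjusted p = 3.73e-08) and Cholesterol biosynthesis (23 genes, median 1.21, adjusted p = 8.96e-08) were among the higher. Intraflagellar transport, the traffic within cilia (38 genes, median -0.60, adjusted p = 0.000193), and Complement cascade (19 genes, median -0.95, adjusted p = 0.005) were among the lower. The count of lower pathways was 19 without PSC library 2 and 13 without PSCN library 2, and with PSC library 3 as the only PSC library there were 25 higher and 12 lower.

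The authors' deposited table of the same comparison lists 891 genes higher and 1839 lower at an adjusted p under 0.05, from 22710 genes with an adjusted p. It gives NSD3 a log2 fold change of 3.72 and an adjusted p of 3.28e-15. The only edgeR call, GM47308, is also higher there, with an adjusted p of 2.86e-27. Across the 20986 genes in both tables the log2 fold changes had the same sign in 99.6%, and Pearson's r and Spearman's rho across genes both rounded to 1, genes not being independent replicates. Of the 2585 genes called in the authors' deposited table that edgeR tested, 2559 had an unadjusted p under 0.05 in edgeR, all with the same sign. In the authors' deposited table, 20 of the 22 ciliated genes, 14 of the 16 B cell genes and 12 of the 15 club cell genes are lower, and 26 of the 43 ribosomal protein and 15 of the 24 cholesterol genes are higher. Of squamous differentiation 12 of 31, of the mTORC1 list 18 of 50, of glycolysis 8 of 16 and of the ATF4 list 8 of 21 genes are higher there, and of plasma cells 9 of 16 and of mast cells 5 of 6 are lower. In some lists few or none are called there, with 0 of 25 basal squamous genes, 0 of 40 mitosis genes, 1 of 40 E2F genes (lower), 5 of 45 MYC targets (higher) and 4 of 22 T cell genes (lower).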

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

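The fits with PSC library 3 as the only PSC library, with sex as a covariate, with adjusted deviances and with limma-voom without quality weights were chosen after seeing the data. For the changes below the cause was not tested. In the first of these fits PSC has no spread of its own, so its counts and p-values do not test the groups. Of the 91 genes reported, 90 kept their direction in every setting chosen beforehand and 88 in all settings, and of the 44 lists 31 did in all. All 27 called lists kept their direction in every setting chosen beforehand, and 22 passed in each of the 6 fits without a library and 22 with sex as a covariate. With PSC library 3 as the only PSC library, 21 of the 27 medians came closer to 0 by over 1.5 times or turned. The number of genes higher in PSCN was 1126 with DESeq2, 1788 with limma-voom with quality weights, 3 with the stricter filter, 3 with edgeR with adjusted deviances, and 0 with the replicate block, PSC library 3 as the only PSC library, sex as a covariate or limma-voom without quality weights, and it ranged from 0 to 751 without each library in turn. The number lower was 1834 with DESeq2 and 1238 with limma-voom with quality weights, and ranged from 0 to 1195 without each library. The upper ends of both ranges are without PSC library 3. Fits without PSC library 3 and with DESeq2 shared 424 higher and 847 lower genes. Deviations of same-numbered libraries correlated at 0.19, -0.05 and 0.02 across genes, which are not independent replicates. Those of differently numbered libraries ran from -0.18 to 0.19. Same-numbered libraries were thus not set apart, but with 3 libraries per group such correlations cannot exclude a pairing. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 1. Reactome pathways numbered 0 higher and 0 lower with an estimated correlation, and 25 and 12 with PSC library 3 as the only PSC library, and the lower ones ranged from 13 to 29 without each library. The log2 fold change of NSD3 was 3.72 with DESeq2 (adjusted p = 3.5e-16), 3.76 with limma-voom with quality weights (adjusted p = 0.0215) and 3.21 to 3.95 without each library, with adjusted p from 3.5e-16 to 0.597 over all alternatives.

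Directions of lists are camera's, which can differ in sign from the median log2 fold change. With PSC library 3 as the only PSC library, directions reversed for MTAP (-0.03), FOXA2 (0.06), the SOX2-linked list (median 0.06), the list of the residue NSD3 acts on (-0.04), NF-kappaB cytokines (-0.07), macrophages (0.04), endothelium (median 1), alveolar type 2 (0.34), ciliated cells (0.24), the unfolded protein response (-0.02), neutrophils (0.02) and muscle (0.79). With limma-voom with quality weights they reversed for the partners of NSD3 (0.05), macrophages (-0.16) and alveolar type 1 (-0.94), and with DESeq2 for fibroblasts (0.40) and alveolar type 1 (-0.56). The list of that residue reversed with the stricter filter (-0.08) and with sex as a covariate (-0.10), and the partners of NSD3 with the replicate block (0.03) and with sex as a covariate (0.10). Without each library in turn, values ranged from -0.08 to 0.69 for SOX2, -0.09 to 0.02 for the list of that residue, -0.08 to 0.12 for the partners of NSD3, -0.41 to 0.19 for macrophages, -1.05 to 0.70 for fibroblasts, -1.02 to -0.06 for endothelium, -0.67 to 0.06 for alveolar type 1, 0.03 to 0.20 for growth factor feedback, 0.02 to 0.31 for the unfolded protein response and 0.10 to 0.30 for Polycomb genes. The alveolar type 1 median was 0.86 with PSC library 3 as the only PSC library. Sex as a covariate, added later, called macrophages, endothelium, neutrophils, the SOX2-linked list and muscle (adjusted p = 0.0194, 2.5e-05, 0.000758, 0.0232 and 1.99e-06). The pseudocount alternatives were not run, since the table holds counts.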

Other observations

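Only the counts of other splits by edgeR, camera and DESeq2 were chosen beforehand. The other tests in this part were chosen after the result was seen, including the split count by limma-voom with quality weights. So were the genes of this paragraph and the next. Of the 24 HOX genes tested, which set position along the body axis, 10 had all 3 PSCN libraries above all 3 PSC libraries and 0 had them below, where chance gives 5 percent in one direction and 15.2 percent of all genes tested had them above. With edgeR, 7 passed adjusted over HOX genes alone, including HOXD8 (log2 fold change 3.57, SE 0.50, adjusted p = 0.00898) and HOXC13 (6.55, SE 1.56, adjusted p = 0.0222). HOXA10 had no count in PSC and stood at 5.34, 2.73 and 1.34 CPM in PSCN libraries 1 to 3. The transcription factors FOXD1 and TBX15 were higher in each PSCN library than in any PSC library without passing over all genes, with FOXD1 at 0.423 ± 0.151 CPM in PSC and 10 ± 6.05 CPM in PSCN (SD, n = 3 each) and TBX15 at 0.281 ± 0.146 and 9.65 ± 6.29 CPM.

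Immunoglobulin genes as a family had a median log2 fold change of -1.71 over 174 tested, and 65 were lower in all 3 PSCN libraries against 1 higher. Among all 21201 genes tested, 2835 were lower and 3231 higher in this way. PROM1, a membrane glycoprotein of epithelial and progenitor cells, stood at 108 ± 46.1 CPM in PSC and 3.85 ± 1.92 CPM in PSCN (SD, n = 3 each), and the chloride channel CFTR at 37.8 ± 13.5 and 3.21 ± 1.23 CPM. Heart muscle transcripts were concentrated in PSC library 1, with the myosin MYH6 at 1293.8 CPM and the actin ACTC1 at 203.1 CPM, against at most 9.26 and 11.2 CPM in the other 5 libraries.

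The 6 libraries form 10 splits into 3 and 3, too few for a share under 0.05. By edgeR, 2 of the 10 splits gave as many genes as the real 1, and the highest other count was 1. For lists it was 4 of 10 (real 27, highest other 31), for Reactome pathways 2 of 10 (real 298, highest other 373) for DESeq2 1 of 10 (real 2960, highest other 1961) and for limma-voom with quality weights 1 of 10 (real 3026, highest other 1). The split of PSC libraries 1 and 2 with PSCN library 1 against the rest gave the 1961 genes, which points to a structure of the samples in which PSC libraries 1 and 2 stand apart.

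The lower ciliated, club, B cell and mast cell lists in PSCN could come from a lower share of non-tumour tissue in those biopsies. The mean score of these 4 lists changed by -2.79 on the log2 scale and that of the alveolar type 1, macrophage, endothelial and fibroblast lists by -0.14. The difference of -2.65 (SE 0.52) decides nothing, because the lists were picked by whether they were called, so a lower non-tumour share and a different mix of cell types remain open. With sex as a covariate the 4 lower lists passed, while 5 other called lists did not, but the group difference in that fit rests on PSC library 1, since only 1 PSC library and all 3 PSCN libraries came from male mice. The sex of the mice remains open too, and an effect of NSD3 T1242A was not separated from these. The same holds for the squamous and growth lists that rose.

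RPS2 had a log2 fold change of 4.91 and its pseudogene RPS2-PS10 one of -1.52, while the pseudogene RPS2-PS6 rose by 1.87 (SE 0.24), from 9.33 ± 2.18 CPM in PSC to 34.1 ± 4.76 CPM in PSCN. The summed counts of RPS2 and its pseudogenes changed by 0.67 (SE 0.26), against a median of 0.71 for the other ribosomal protein genes, which is consistent with reads moving between RPS2 and its pseudogenes.

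Bone matrix genes stood out in PSCN library 1, with IBSP at 2035 CPM against at most 0.82 CPM elsewhere and COL1A1 at 19229.4 CPM. Osteoblast markers lay above all other libraries in 13 of 13 genes, and 9 of 11 osteoclast markers did, with a median log2 ratio to the highest other library of 1.52 (error 0.49), so cells of bone may be present in this biopsy. Marrow precursor markers had a median of -1.23 (error 0.31), with 2 of 18 above all other libraries. This does not decide on bone marrow, because a ratio to the highest other library is mostly negative for genes that do not differ. Many of these markers were also near the floor, and HBB was highest in PSC library 2 at 166.1 CPM. Cartilage markers had a median of -0.37 with 4 of 10 above all other libraries, among them ACAN at 19.4 CPM against at most 0.08 CPM. Fibroblast genes other than collagens exceeded PSCN libraries 2 and 3 by a median of 1.44 (error 0.50) on the log2 scale and COL1A1 by 5.43. The excess of COL1A1 was thus not matched by the median of these genes. This does not decide on a higher share of lung fibroblasts, because COL1A1 was picked for its high level and that median was raised too. Whether the bone-like cells are tumour, stroma or nearby bone was not tested, and CDKN2B, deleted in the model, stood at 86.1 CPM in this library alone.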
